A study of Homo sapiens with 2 samples.

How the data were processed

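LP-1 is an established human multiple myeloma cell line. Untreated LP-1 cells were profiled by CUT&Tag, per the labels' protocols: cells bound to beads were incubated with an antibody against PSMD14 or against NSD2 and then with a secondary antibody, and a protein A-Tn5 transposase cut and tagged the DNA next to the bound antibody. The released fragments were amplified and sequenced as read pairs on an Illumina NovaSeq, per the labels' protocols. There was 1 library per antibody. The labels name no repeat library and no control library, such as one made with a non-specific antibody.

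Reads were handled with fastp 0.19.6, Bowtie2 and deepTools on the human build GRCh38 (hg38), per the submitters' processing notes, which name these tools without their order or settings. The peak caller, its threshold and any background model are not given in the sources used here. The authors deposited 1 peak list per library. Each list gives a chromosome, a start, an end and a running name for each peak. The layout has 10 columns, and columns 5 to 10 are empty in every line of both deposited lists, so no height, enrichment, score or p-value of a peak could be used. Starts were taken as counted from 0, as in a narrowPeak layout, and are printed counted from 1. Peaks within a list do not overlap each other. The files give no read counts, so the sequencing depth of both libraries is unknown, and a longer list can come from a deeper library or a looser threshold as well as from more binding sites.

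Gene positions came from an NCBI RefSeq gene table of the same build, with 59098 genes placed on chromosomes 1 to 22 and X, of which 19974 are protein-coding. The table gives the outer ends of each gene and its biotype, without strand, transcripts or exons, and no genome sequence was used. The planned unit was the promoter, within 1000 bp of any transcript start. It was replaced by the gene end, within 1000 bp of either annotated outer end of a protein-coding gene. Alternative start sites inside a gene are therefore counted as inside, and exons, introns and untranslated regions are not told apart. For a subset of genes the 5′ end could be inferred from names: a divergent transcript named after the gene and lying within 5000 bp of only 1 of its ends, or a readthrough locus that names the gene and its neighbour in order. Each peak was put in the first matching class by its midpoint: gene end, inside a protein-coding gene, at another annotated gene, or between genes. Peaks on chromosomes 1 to 22 and X were analysed; the rest entered only the alternative that used every sequence and the checks for technical causes.

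Peaks of the libraries counted as shared when they had at least 1 bp in common. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error alone and treat peaks as independent. Observed shares were set beside 1000 random placements of the same peaks, with their widths, on their own chromosomes, within bins of 1 Mb that held a gene or a peak. A gene had a gene-end peak when at least 1 bp of a peak lay in either of its windows, and the number of genes with both was set beside n1 × n2 / N. With 1 library per antibody, no p-value was computed for a difference between the libraries, and no spread between replicates can be given.

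Before the data were examined, 21 gene lists were fixed from general knowledge of the proteins, of plasma cells and of other cell types. All 389 distinct symbols were found among the protein-coding genes. The share of each list with a gene-end peak was set beside 10000 random lists of the same size drawn from all protein-coding genes. A list is called above or below random lists where it lay outside their central 95%, a mark set after the values were seen. Genes are not replicates, so these positions describe the libraries at hand.

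The genes named in the report follow a rule fixed at the same time: PSMD14, NSD2, RELA, MYC, IRF4, PRDM1, XBP1, CCND2, FGFR3 and MCL1 whatever their values; the 10 genes ranked highest in both libraries; the 5 ranked highest in each library among genes without a gene-end peak of the other; and from each list the 2 members ranked highest in both libraries (or, where fewer than 2 had both, in 1 of them) and the first 2 in alphabetical order with neither. The rule ranked peaks by score. Since the lists hold no score, peaks were ranked by width within each list, taking the lower of a gene's ranks in the libraries. Some genes that the rule selects are not reported here.

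Alternative settings were fixed together with the lists, and those that were run changed the overlap that counts as shared (50% of both peaks, or midpoints within 200 bp), the window (500 or 3000 bp), the sequences used, the random placement and the assignment of peaks to genes. The planned stricter threshold by score, the equal number of strongest peaks, the single 5′ start per gene and random lists matched on CpG content were not run, because they need a score, strand or sequence. Settings chosen after seeing the data took their place: the wider 50% of each list, the widest NSD2 peaks in the number of the PSMD14 list, placement within 100 kb, the window of 500 bp for the gene lists, and random lists matched on the number of peaks in the surrounding 1 Mb. Placements for settings that change the peak set were drawn 100 times.

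The overlap and placement code was tested on simulated data. The 77351 PSMD14 peaks were scattered at random and 0, 20 or 40% of them were given an exact copy as partner in a simulated NSD2 list. After correction for random overlap, the recovered shares were 0.158%, 20.1% and 40.0%. Reported shares of the real peaks carry no such correction. Partners that overlap only in part were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.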

Results

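PSMD14 is the deubiquitinase subunit in the lid of the proteasome's regulatory particle, and NSD2 is a histone methyltransferase that acts on lysine 36 of histone H3. The series set out to find the genes that these proteins may regulate in LP-1, a multiple myeloma line that carries the t(4;14) translocation, which places NSD2 under control of the immunoglobulin heavy-chain locus. CUT&Tag peaks were available for 1 PSMD14 library and 1 NSD2 library of untreated cells. There were no replicates, the labels name no control library, and the depth is unknown. The values below therefore describe these libraries, and their intervals cover counting error only. Without a control library, sites bound by PSMD14 or NSD2 cannot be told apart from open chromatin that the transposase cuts with any antibody. This holds for every count of peaks and genes below.

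The PSMD14 library had 77351 peaks on chromosomes 1 to 22 and X, with a median width of 432 bp (quartiles 344 and 634 bp), covering 41.4 Mb. The NSD2 library had 100659 peaks with a median width of 461 bp (quartiles 353 and 690 bp), covering 57.6 Mb.

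The first question was where each protein's peaks lay. Both libraries were concentrated at the ends of protein-coding genes. Of the PSMD14 peaks, 14.2% (95% interval 13.9 to 14.4%) had their midpoint within 1000 bp of a gene end, against a mean of 2.88% for random placements, a 4.92-fold excess. Of the NSD2 peaks, 12.8% (12.6 to 13.1%) did, against 2.70%, a 4.76-fold excess. Peaks between genes were depleted in both, at 27.7% of PSMD14 and 22.9% of NSD2 peaks against random means of 39.0% and 39.4%.

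The libraries differed inside genes. NSD2 peaks lay inside protein-coding genes in 53.0% of cases (52.7 to 53.3%), 1.24 times the random mean of 42.8%. PSMD14 peaks did so in 44.9% (44.6 to 45.3%), 1.04 times the random mean of 43.2%. The PSMD14 gene itself showed the difference, with 0 PSMD14 and 11 NSD2 peaks more than 1000 bp inside its ends. The NSD2 gene had 13 of each. The order of the gene-end shares depended on which peaks were used: with only the NSD2 list limited to its widest peaks, as many as in the PSMD14 list, 14.7% of NSD2 peaks lay at gene ends, above the 14.2% of PSMD14. In the wider 50% of both lists PSMD14 stayed above, at 20.5% against 18.1%. Wide peaks were more often at gene ends, so that limit changed width as well as number.

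**Figure D1:**
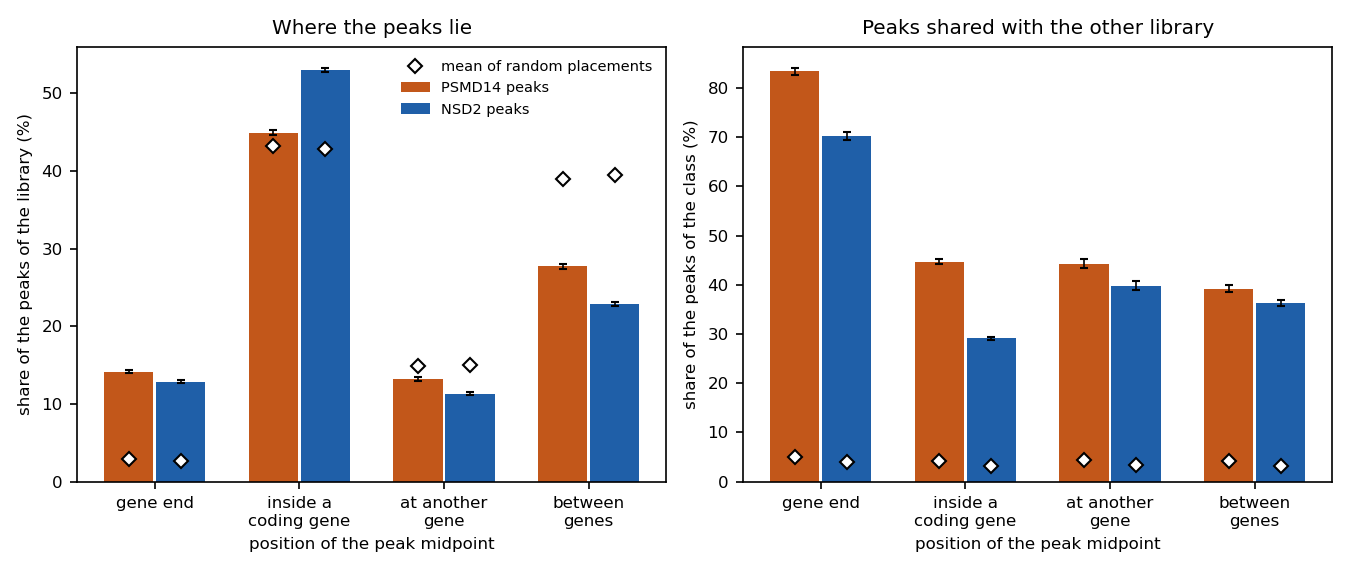
Left, the share of PSMD14 (orange) and NSD2 (blue) peaks in each class of position, in percent; right, the share of the peaks of each class that overlapped a peak of the other library. Error bars are exact 95% binomial intervals and diamonds are means of 1000 random placements. Gene-end peaks were shared most often, at 83.4% for PSMD14 and 70.3% for NSD2.

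The outer ends used here do not say where transcription starts, so genes whose 5′ end follows from the name of a neighbouring transcript were examined apart. Among 524 genes with a named divergent transcript, 74.6% (70.7 to 78.3%) had a PSMD14 peak at the 5′ end and 10.9% (8.34 to 13.9%) at the 3′ end. For NSD2 the shares were 80.3% (76.7 to 83.7%) and 22.3% (18.8 to 26.1%). In 235 genes taken from readthrough loci, PSMD14 peaks were at the 5′ end of 61.7% and the 3′ end of 18.3%, and NSD2 peaks at the 5′ end of 67.2% and the 3′ end of 23.4%. These subsets were chosen after the data were seen and need not stand for all genes. Over all protein-coding genes, 57.2% had a PSMD14 peak and 62.1% an NSD2 peak at either end. In readthrough loci the 3′ end of a gene can also lie near the 5′ end of its neighbour.

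The second question was how far the sites of PSMD14 and NSD2 coincided. Of the PSMD14 peaks, 37587 overlapped an NSD2 peak, a share of 48.6% (48.2 to 48.9%). Random placements gave 4.36% on average (4.08 to 4.61% over 1000 placements), so the observed share was 11.2 times higher. In the other direction 37510 NSD2 peaks overlapped a PSMD14 peak, 37.3% (37.0 to 37.6%) against 3.35%, which was 11.1 times higher. In base pairs, 20.4 Mb of the 78.6 Mb covered by either library was covered by both.

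Sharing was highest at gene ends, at 83.4% of PSMD14 peaks (82.7 to 84.1%) and 70.3% of NSD2 peaks (69.5 to 71.1%). Inside protein-coding genes 44.7% of PSMD14 and 29.1% of NSD2 peaks were shared, and between genes 39.2% and 36.4%. Shared peaks were wider: the median was 565 bp against 374 bp for unshared PSMD14 peaks, and 676 bp against 398 bp for unshared NSD2 peaks. From the narrowest to the widest 20% of each list, the shared portion went from 25.2 to 85.4% of PSMD14 peaks and from 14.6 to 76.7% of NSD2 peaks. The excess depended on how peaks were placed and which were used: for PSMD14 it was 7.33-fold when gene-end peaks were placed at gene ends and all others elsewhere, 6.32-fold with placements within 100 kb, and 18.9-fold in the wider 50% of both lists.

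The third question was which genes carried peaks of PSMD14, NSD2 or both. Of 19974 protein-coding genes, 11433 (57.2%) had a PSMD14 gene-end peak and 12398 (62.1%) an NSD2 gene-end peak. Both were present at 10386 genes (52.0%, 51.3 to 52.7%), 1.46 times the 7097 that independent lists would give. This counts peaks at different ends of a gene too. At 10016 of these genes (50.1% of all) a PSMD14 gene-end peak overlapped an NSD2 peak, which could itself lie outside the window. A PSMD14 gene-end peak without an NSD2 gene-end peak was found at 1047 genes, the reverse at 2012, and neither at 6529. Such genes could still have a peak of the other library outside the windows. NSD2 gene-end peaks were present at 90.8% of the genes with a PSMD14 gene-end peak and at 23.6% of the genes without one. When each peak was assigned to its nearest gene instead, 15770 genes had both, 1.10 times the number from independent lists. Of all protein-coding genes, 16678 then had a PSMD14 peak and 17212 an NSD2 peak, which left little room for a higher ratio.

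RELA, which encodes the p65 subunit of NF-kB, carried overlapping PSMD14 and NSD2 peaks at both of its ends. On chromosome 11 the PSMD14 peaks spanned 65652729 to 65653519 and 65663107 to 65664078, and the NSD2 peaks 65652763 to 65653878 and 65663173 to 65664102; the gene runs from 65653601 to 65663857. MYC, a transcription factor that drives growth in myeloma, had a PSMD14 peak of 1573 bp (chromosome 8, 127735180 to 127736752) and an NSD2 peak of 678 bp (127735219 to 127735896) at its lower end, and overlapping peaks inside the gene. The PSMD14 gene had overlapping peaks of both libraries at its lower end on chromosome 2, at 161308191 to 161308917 for PSMD14 and 161307928 to 161308917 for NSD2. At the lower end of the NSD2 gene on chromosome 4, the peaks spanned 1869937 to 1870531 for PSMD14 and 1869947 to 1870523 for NSD2.

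IRF4, a transcription factor of plasma cells, had overlapping gene-end peaks of 566 bp for PSMD14 and 463 bp for NSD2. MCL1, an anti-apoptotic gene on which myeloma cells depend, had 2 PSMD14 peaks and 2 NSD2 peaks at its higher end, overlapping in pairs. XBP1, which drives the secretory program of plasma cells, had PSMD14 peaks of 1255 and 313 bp at its higher end and an NSD2 peak of 272 bp there, which overlapped neither. The wider PSMD14 peak overlapped an NSD2 peak of 276 bp inside the gene (chromosome 22, 28798384 to 28798659). CCND2, which encodes cyclin D2, had PSMD14 peaks of 1444 and 686 bp at its lower end, of which the wider overlapped an NSD2 peak of 368 bp. It also held 6 NSD2 peaks inside the gene and 0 of PSMD14.

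FGFR3, the receptor gene near NSD2 on chromosome 4, carried a PSMD14 peak of 881 bp at its lower end and an NSD2 peak of 1579 bp at its higher end. Each of these overlapped a peak of the other library that lay outside the window, and 2 pairs of peaks overlapped inside the gene. PRDM1, the master regulator of plasma cell differentiation, had no PSMD14 peak at its annotated outer ends and an NSD2 peak of 357 bp at the lower one. Inside PRDM1 there were 5 PSMD14 and 9 NSD2 peaks, including overlapping peaks at 106085881 to 106086323 for PSMD14 and 106085897 to 106086270 for NSD2 on chromosome 6.

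**Figure D2:**
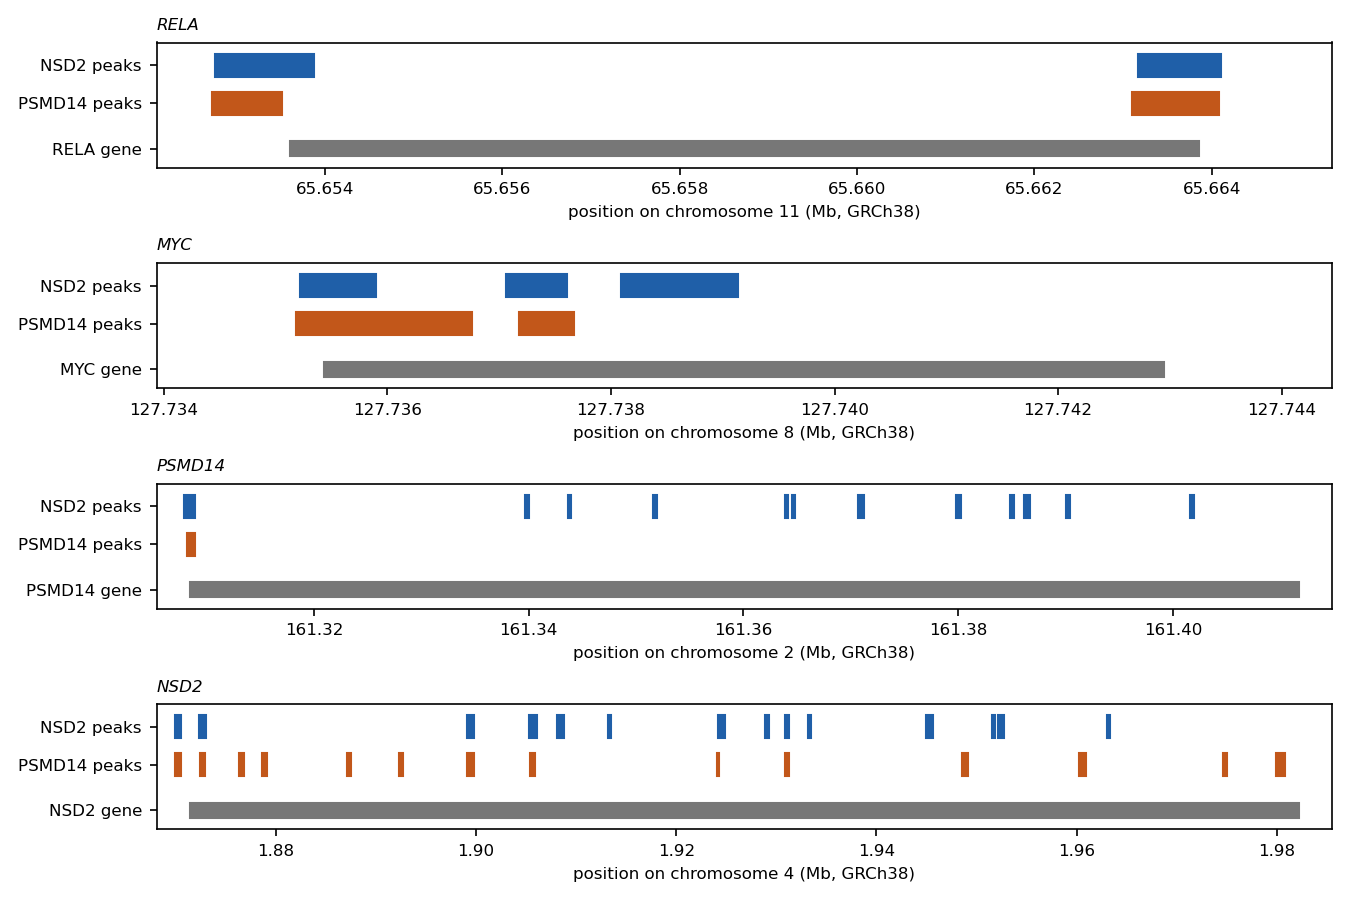
Peaks of the PSMD14 (orange) and NSD2 (blue) libraries over RELA, MYC, PSMD14 and NSD2, drawn to scale on GRCh38 positions in Mb, with the annotated gene in grey. RELA has overlapping peaks of both libraries at both ends, and the PSMD14 gene holds 11 NSD2 peaks and 0 PSMD14 peaks beyond 1000 bp inside its ends.

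The genes with the widest gene-end peaks in both libraries were WDR74, ADAMTSL4, CTC1, ETV1, PRDX6, the histone gene H4C15, and pairs of neighbours that share a peak, AIRIM with CDCA8 and H2BC18 with H3C13. At WDR74, a ribosome biogenesis gene on chromosome 11, the peaks measured 2799 bp for PSMD14 and 3253 bp for NSD2. The peak between AIRIM and CDCA8, a mitotic gene, measured 2774 and 3230 bp. The peak at H2BC18 and H3C13 measured 3257 and 2638 bp. ETV1, an ETS-family transcription factor, had peaks of 2798 and 2590 bp, and PRDX6, a peroxiredoxin, of 2394 and 2788 bp.

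Among genes with a PSMD14 gene-end peak and none of NSD2, the widest peaks were at SV2A (2163 bp), PCNT (2020 bp), TPTEP2-CSNK1E (1812 bp), ACP5 (1662 bp) and GDF11 (1588 bp). At ACP5 the widest PSMD14 peak overlapped no NSD2 peak; at the other 4 genes it overlapped an NSD2 peak that lay just outside the window. Among genes with an NSD2 gene-end peak and none of PSMD14, the widest were at ZC3H12A (2543 bp), NAF1 (2150 bp), NANOS1 (2067 bp), MOB1B (2004 bp) and LRP2 (1994 bp). The NSD2 peaks at NAF1 and MOB1B overlapped no PSMD14 peak, and those at ZC3H12A, NANOS1 and LRP2 overlapped one outside the window.

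The fourth question was which gene groups carried the peaks. A gene-end peak here can lie at the 5′ or the 3′ end of a gene, and at the end of an adjoining gene as well. Groups used by every growing cell, the proteasome's own genes among them, were nearly complete in both libraries. Of 32 proteasome subunit genes, 29 had a PSMD14 gene-end peak (90.6%, 74.98 to 98.0%) and 32 an NSD2 gene-end peak (100%, 89.1 to 100%). PSMA2 had peaks of 1436 bp for PSMD14 and 1688 bp for NSD2, and PSMB3 of 1571 and 1458 bp. All 20 cell cycle genes, such as CDK4 and AURKA, had both. Of 25 cytosolic ribosomal protein genes 24 had both, with RPL10A and RPL23 first by the lower of their width ranks in the libraries. RPL13, with overlapping peaks inside the gene only, was the exception. Of 20 DNA repair genes 18 had a PSMD14 peak and 20 an NSD2 peak, with BRCA1 carrying wide peaks of both.

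Genes of the unfolded protein response, which plasma cells need to secrete antibody, had both peaks in 18 of 19 cases, led by HSP90B1 (2236 bp for PSMD14, 2313 bp for NSD2) and ERN1; PDIA6 had neither at its outer ends but 4 PSMD14 and 7 NSD2 peaks inside. Of 22 deubiquitinase and ubiquitin genes, 18 had a PSMD14 and 20 an NSD2 gene-end peak, with MDM2 and UCHL5 carrying both. Of 20 histone methylation and acetylation enzymes, 18 had both, among them KMT2A and KDM2A, while CREBBP and KDM2B had neither at their outer ends but held 13 and 7 PSMD14 and 17 and 8 NSD2 peaks inside. Interferon and antigen presentation genes had a PSMD14 peak in 17 of 19 cases and an NSD2 peak in 18. TAP1 and PSMB9, neighbours in the MHC region, shared a peak of 2110 bp for PSMD14 and 2150 bp for NSD2, and IFIT3 had neither at its outer ends but a PSMD14 peak of 2047 bp inside, overlapping 2 NSD2 peaks.

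NF-kB pathway genes had a PSMD14 gene-end peak in 17 of 21 cases (81.0%, 58.1 to 94.6%) and an NSD2 gene-end peak in 19 (90.5%, 69.6 to 98.8%). CHUK, the IKK-alpha kinase gene, had peaks of 2251 bp for PSMD14 and 2266 bp for NSD2 at its lower end. At its higher end they measured 500 and 634 bp. At NFKBIE, an NF-kB inhibitor gene, the widest PSMD14 gene-end peak (2339 bp) lay at the higher end. The widest NSD2 gene-end peak there (1389 bp) lay at the lower end. Which end is the 5′ end was not known for these genes. IKBKG and TAB2 had neither at their outer ends, and held 2 and 0 PSMD14 and 4 and 4 NSD2 peaks inside. Of the 24 myeloma driver genes, 18 had a PSMD14 peak and 21 an NSD2 peak. CKS1B had peaks of 1778 and 1770 bp and MAF of 1249 and 1379 bp, whereas CCND1 and IKZF1 had neither at their outer ends. Inside, IKZF1 held 11 PSMD14 and 12 NSD2 peaks, of which 10 and 8 were shared, and CCND1 held 1 of each, not shared. Of 16 plasma cell identity genes, 13 had a PSMD14 peak and 14 an NSD2 peak. CD27 and TNFRSF17, the gene for BCMA, came first by the lower of their width ranks in the libraries. The gene-end peaks of CD27 lay at its higher end only. For PSMD14 alone, XBP1 had a wider gene-end peak (1255 bp) than TNFRSF17 (1187 bp). FKBP11 and TENT5C had neither at their outer ends. Inside FKBP11 a PSMD14 peak of 1094 bp overlapped 2 of 3 NSD2 peaks. The list of neighbours of NSD2 on the short arm of chromosome 4 holds 12 genes, NSD2 itself among them. Of these 10 had both, including LETM1. With a window of 500 bp, 5 had a PSMD14 peak and 6 an NSD2 peak. NAT8L and MXD4 had neither at their outer ends but held overlapping peaks inside. Of 18 replication-dependent histone genes 14 had both, with H2AC4 and H3C2 sharing a peak of 2409 bp for PSMD14 and 2352 bp for NSD2, and H2AC8 and H2BC8 had neither.

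Lists of other lineages had smaller shares of genes with a gene-end peak than all protein-coding genes, although T and NK markers in both libraries, myeloid, erythroid and stromal markers for PSMD14 and epithelial markers for NSD2 lay inside the range of random lists. Of 16 neuron and muscle markers, 2 had a PSMD14 peak, SYT1 and DES, and 4 an NSD2 peak; ACTN2 and CKM had neither at their outer ends, though inside ACTN2 a PSMD14 peak of 1207 bp overlapped an NSD2 peak of 1270 bp. Of 18 olfactory receptor genes, 2 had a PSMD14 peak and 2 others an NSD2 peak, such as OR10G2 for PSMD14 and OR4C3 for NSD2, and OR1A1 and OR1D2 were among those with neither. Stromal and endothelial markers had a PSMD14 peak in 5 of 15 cases and an NSD2 peak in 2. COL1A1 had both, and COL1A2 and COL3A1 neither. CDH5 had a PSMD14 gene-end peak and none of NSD2, but held 6 NSD2 peaks inside. Epithelial and liver markers had a PSMD14 peak in 3 of 15 cases, including KRT5 and KRT8, and an NSD2 peak in 6 (0 of 15 for PSMD14 with 500 bp, and 2 for NSD2 in the wider 50%), with ALB and CDH1 without either at their outer ends, though CDH1 held 7 PSMD14 and 6 NSD2 peaks inside, 2 of each shared. Erythroid and platelet markers had a PSMD14 peak in 4 of 14 cases and an NSD2 peak in 3, with both at GP9 and SLC4A1 and neither at the outer ends of EPB42, which held 2 PSMD14 peaks and 1 NSD2 peak inside, or of GATA1. Myeloid markers had a PSMD14 peak in 6 of 16 cases and an NSD2 peak in 5, with both at FCGR3A and S100A9 and neither at CD14 and CD163. T and NK cell markers had a PSMD14 peak in 6 of 16 cases and an NSD2 peak in 7. CD3E and NCAM1 had both. CD3G and CD4 had neither at their outer ends, though CD4 held 2 PSMD14 peaks inside. These counts do not tell 5′ from 3′ ends. At CD3E, S100A9 and DES the gene-end peaks lay at the higher end only, and at FCGR3A, SLC4A1 and KRT8 at the lower end only.

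Genes of earlier B cell stages, which plasma cells silence, had a PSMD14 gene-end peak in 5 of 16 cases (31.2%, 11.02 to 58.7%) and an NSD2 gene-end peak in 8 (50%, 24.7 to 75.3%). EBF1 and SPIB had both, and CD22 had neither. This share depended on the window: within 3000 bp of a gene end, 14 of the 16 genes (87.5%) had a PSMD14 peak and 12 (75%) an NSD2 peak. More of all protein-coding genes had a peak too, from 11433 to 14068 for PSMD14 and from 12398 to 14766 for NSD2. Even so, the list went from above 0.83% to above 89.4% of random lists for PSMD14, and from above 10.8% to above 41.35% for NSD2. T and NK cell markers rose to 11 of 16 (68.8%) for PSMD14, above 32.9% of random lists. For NSD2, stromal markers rose to 8 of 15 (53.3%) and erythroid and platelet markers to 8 of 14 (57.1%). Those lay above 2.44% and 4.63% of random lists. With 500 bp the NSD2 count of stromal markers was 0 and that of myeloma drivers 16 of 24 (66.7%), and the PSMD14 count of histone enzymes was 12 of 20 (60%). In the wider 50% 1 neuron and muscle marker had an NSD2 peak.

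Against random lists of the same size, 9 lists lay above the central 95% for PSMD14: the proteasome, NF-kB, unfolded protein response, deubiquitinase, histone enzyme, cell cycle, DNA repair, ribosomal protein and interferon lists. The same 9 and the myeloma drivers lay above it for NSD2. Below it lay 3 lists for PSMD14 (epithelial and liver, neuron and muscle, olfactory receptors) and 5 for NSD2 (myeloid, erythroid and platelet, stromal and endothelial, neuron and muscle, olfactory receptors). The plasma cell list held more PSMD14 genes than 95.9% and more NSD2 genes than 97.2% of random lists, and its place changed with the setting: for PSMD14 it ranged from 89.98% with matched lists to 99.5% in the wider 50%. Under every setting tried for the lists, 4 stayed above for PSMD14 (proteasome, unfolded protein response, cell cycle and ribosomal proteins) and 6 for NSD2 (these and the deubiquitinase and DNA repair lists). Neuron and muscle markers and olfactory receptors stayed below for both libraries.

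The other calls depended on the setting, and some lists left the range of random lists while others entered it. With a window of 3000 bp the NF-kB and interferon lists no longer lay above for either library (NF-kB above 90.7% of random lists for PSMD14 and 94.3% for NSD2; interferon above 94.7% and 97.4%), nor did DNA repair for PSMD14 (96.1%). Below for NSD2 there remained 2 lists, neuron and muscle and olfactory receptors, while stromal markers joined those below for PSMD14. With 500 bp the NF-kB list for PSMD14 (96.6%), the histone enzymes for PSMD14 (77.1%) and NSD2 (95.1%) and the myeloma drivers for NSD2 (84.4%) no longer lay above. Replication-dependent histones now did for PSMD14 (98.6%), and erythroid and stromal markers joined those below, 5 lists in all. In the wider 50% of peaks the deubiquitinases no longer lay above for PSMD14 (91.1%). The plasma cell list (99.5%) and the neighbours of NSD2 (98.7%) now did for PSMD14, and those neighbours (97.52%) and the replication-dependent histones (97.8%) for NSD2. The neighbours lay above 20.9% and 27.3% of random lists with 500 bp, and 66.98% and 66.0% with matched lists. In the wider 50% of peaks the lists above numbered 10 for PSMD14 and 12 for NSD2. Among those below in that setting, erythroid markers took the place of epithelial ones for PSMD14, and epithelial markers that of myeloid ones for NSD2. The latter exchange was also seen with equal numbers. With random lists matched on surrounding peaks the NF-kB list was inside for PSMD14 (95.9%) and the histone enzymes for NSD2 (96.9%). Genes of earlier B cell stages then lay below for PSMD14, with more genes in 97.51% of random lists.

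**Figure D3:**
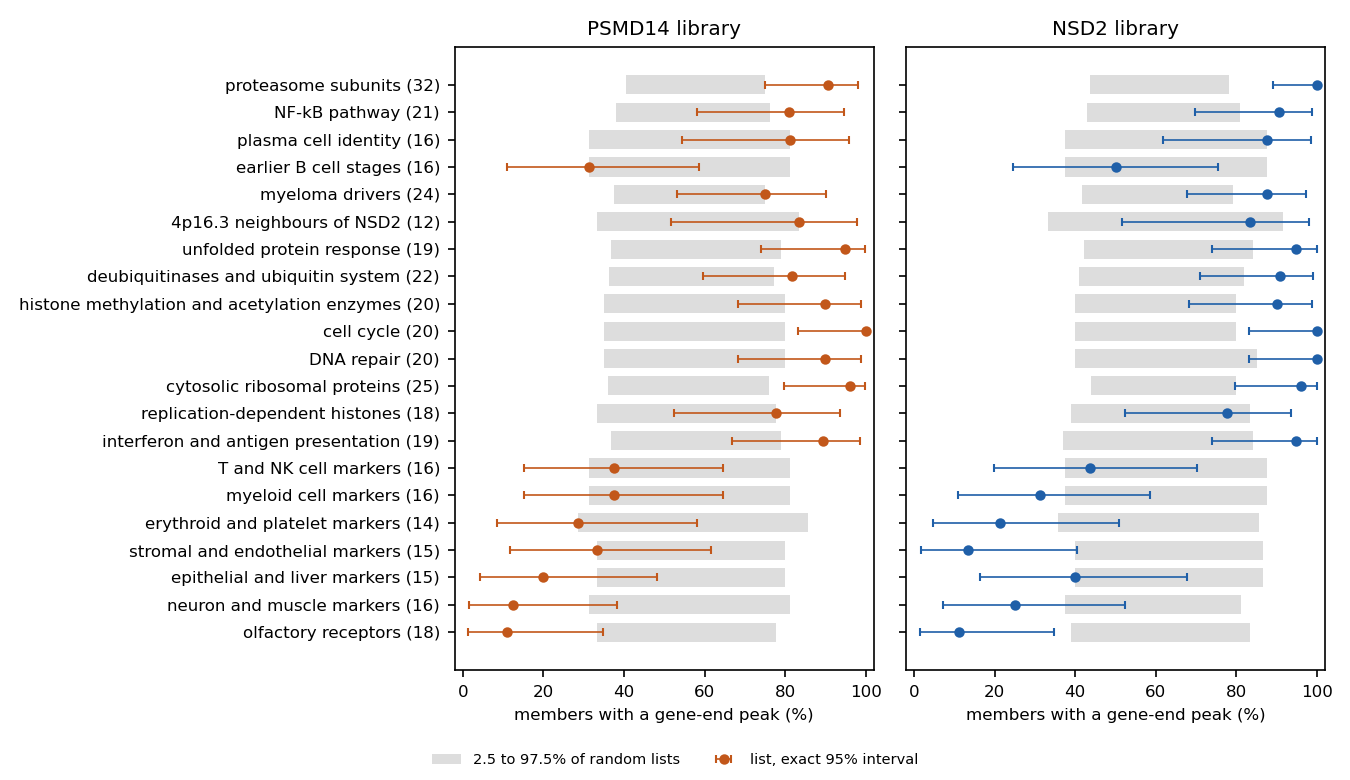
Share of the members of each of 21 gene lists with a gene-end peak in the PSMD14 library (left, orange) and the NSD2 library (right, blue), in percent, with exact 95% binomial intervals; list sizes are in parentheses. Grey bars span the central 95% of 10000 random lists of the same size. Proteasome, cell cycle and ribosomal protein genes sit above the grey bars in both panels and olfactory receptors below.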

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

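Peaks outside chromosomes 1 to 22 and X were left out of the comparisons, apart from the alternative that used every sequence (overlap 48.7% for PSMD14 and 37.5% for NSD2, gene ends 14.05% and 12.8%). All tests weighed here were chosen or given their bounds after the overlap and the peak positions had been seen, although placement of gene-end peaks at gene ends and all others elsewhere had been fixed beforehand. On the mitochondrial genome, which carries no nucleosomes, each list held 5 peaks. They covered 13.55 kb for PSMD14 and 13.6 kb for NSD2, most of that genome, so overlap there was practically fixed. On unplaced and unlocalised contigs there were 675 PSMD14 peaks, of which 60.9% (57.1 to 64.6%) overlapped an NSD2 peak. There were 621 NSD2 peaks on such contigs, of which 67.1% (63.3 to 70.8%) overlapped a PSMD14 peak. On chromosomes 1 to 22 and X the shares were 48.6% and 37.3%. No random expectation was computed for the contigs.

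The overlap of PSMD14 and NSD2 peaks was 11.2 times that of random placement for PSMD14. A common preference for gene ends does not account for all of it, since the excess was 7.33-fold when gene-end peaks were placed at gene ends and all others elsewhere. Preference for the other classes of position was not controlled. Differences in copy number, gene density or mappability between regions broader than 100 kb do not account for all of it either. The excess over placement within 100 kb was 6.32-fold. Differences at a finer scale, such as mappability from peak to peak, were not controlled. Open chromatin that the transposase cuts with any antibody stays open as an explanation: in the widest 20% of PSMD14 peaks 14.6% had no NSD2 partner, and without a control library this cannot be told apart from PSMD14 and NSD2 binding the same sites. The gene-end excess and the gene-list shares of both libraries have the same limit, the lack of a control library. DNA molecules counted in both libraries, taken up below, could add to the overlap as well, and this was not tested. Joint binding of PSMD14 and NSD2, the biological explanation, was not tested in itself.

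Where PSMD14 and NSD2 peaks overlapped, their edges fell on the same base more often than at neighbouring offsets. Of 76088 edges in 38044 overlapping pairs, 3281 (4.31%) coincided exactly, 13.4 times the mean for offsets of up to 20 bp on either side, and in 88 pairs both edges did. NCAM1 shows it, with a peak from 112961179 to 112961846 on chromosome 11 in both lists; it was singled out after its values were seen. Offsets of 5 and 10 bp held 2.57 times the edges of the other offsets, a pattern that cutting by the same transposase at preferred positions may leave, although these offsets were picked from the same values. DNA molecules counted in both libraries, through carry-over or misread sample indexes, could also give the 13.4-fold excess. They could add to the overlap of the peaks itself too, the named genes included. The lists alone cannot be used to tell these explanations apart, and the reads were not used here.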

How the results depend on the processing

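The wider 50% of each list, the equal number of NSD2 peaks, placement within 100 kb, random lists matched on surrounding peaks, the 500 bp window for lists and every alternative of the ratio inside genes were chosen after seeing the data. Of 81 alternative values for the comparisons, 51 stayed within the interval or within 1.5 times the reported count and 30 moved. The PSMD14 share overlapping NSD2 was 56.6% in the wider 50%, 44.3% with equal numbers, 35.7% with 50% of both peaks in common, 36.4% for midpoints within 200 bp and 42.8% away from gene ends. The NSD2 share was 43.4%, 44.0%, 27.4%, 28.0% and 32.4%. The fold over random placement for PSMD14 was 18.9 in the wider 50%, 12.3 with equal numbers, 10.04 away from gene ends, 7.33 with gene-end and other peaks placed apart and 6.32 within 100 kb, and for NSD2 18.9, 12.3, 9.94, 7.29 and 6.30. The gene-end share of PSMD14 peaks was 20.5% in the wider 50%, 9.51% with a window of 500 bp and 22.6% with 3000 bp. For NSD2 it was 18.1%, 8.03% and 21.2%, and 14.7% with equal numbers, the 1 setting that put NSD2 above PSMD14. Assigning peaks to the nearest gene gave 15770 genes with both, and with a 3000 bp window 2 lists lay below random lists for NSD2, and with 500 bp 5 did for PSMD14. A wider window raises the gene-end share of peaks by construction. Random lists used the same window as the gene lists, so the changes in list calls do not follow from it alone. Their cause was not tested. The wider 50% and equal numbers changed width together with number, and the cause was not tested. Of 147 alternative list shares, 130 stayed within their interval and 17 moved. Intervals from lists of 12 to 32 genes are wide, so staying inside them says little. The PSMD14 share of the deubiquitinases stayed inside at 63.6% in the wider 50%, yet the list no longer lay above random lists. The ratio inside genes was 1.60, 1.57 and 1.497 with equal numbers, the wider 50% and genes of at least 100 kb, with gene classes set by the full lists. The stricter threshold and equal number of peaks by score, 1 start per gene and CpG-matched lists were not run. No paired analysis was possible because there was 1 library per antibody. Unknown depth limits every comparison of list length.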

Other observations

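The gene families, genes and tests in this part were chosen after the peak lists had been seen, and none was planned. Genes of the mitochondrial ribosome were nearly complete, with a PSMD14 gene-end peak at 73 of 77 and an NSD2 gene-end peak at 75. Genes of respiratory complex I had a PSMD14 peak at 43 of 46 and an NSD2 peak at 43, and translation initiation factors at 47 and 52 of 55. Zinc finger genes with ZNF symbols had a PSMD14 peak at 343 of 517 (66.3%, 62.1 to 70.4%) and an NSD2 peak at 383 (74.1%, 70.1 to 77.8%). At the other end lay the 392 olfactory receptor genes, with 28 and 27, and the 65 protocadherin genes, with 6 and 9. HOX genes, the developmental regulators of body position, had a PSMD14 peak at 15 of 40 (37.5%, 22.7 to 54.2%) and an NSD2 peak at 6 (15.0%, 5.71 to 29.8%). Potassium channel genes went the other way, with 28 of 96 (29.2%, 20.3 to 39.3%) for PSMD14 and 42 (43.8%, 33.6 to 54.3%) for NSD2. These differences were not tested, since there is 1 library per antibody.

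Some long genes held many more peaks of 1 library. GALNT13, a glycosyltransferase gene on chromosome 2, held 12 PSMD14 and 83 NSD2 peaks more than 1000 bp inside its ends. STAG1, a cohesin subunit gene, held 6 and 41, HDAC9 19 and 62, and VPS13B 46 and 96. The reverse was seen at RBFOX1, a neuronal splicing regulator, with 41 PSMD14 and 17 NSD2 peaks, at PTPRN2 with 47 and 25, at PDZD2 with 21 and 5 and at CACNA1D, a calcium channel gene, with 23 and 8. Whole chromosomes differed too: NSD2 peaks per PSMD14 peak ranged from 0.92 on chromosome 19 to 2.10 on chromosome 13, with 1.46 on chromosome 2. Such broad differences were not removed from these gene counts.

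NSD2 peaks were more frequent inside genes that carried gene-end peaks of both libraries. In 3258 such genes of at least 50 kb there were 2.95 PSMD14 and 5.44 NSD2 peaks per 100 kb, or 1.84 NSD2 peaks for each PSMD14 peak. In 2042 genes of that length with neither gene-end peak there were 1.82 and 2.15 per 100 kb, or 1.18 for each. The ratio of these ratios was 1.56 (1.49 to 1.64, 95% bootstrap interval over genes, which are not replicates). It fell with gene length, from 1.76 in genes of 50 to 100 kb and 1.59 in those of 100 to 200 kb to 1.31 in those of 400 kb or more, and the genes with neither were longer on average (411.8 Mb in all, against 485.0 Mb).

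Differences between whole chromosomes do not account for this: the ratio was higher in genes with both gene-end peaks on 23 of 23 chromosomes. Local base composition was not tested, since no genome sequence was used. A candidate explanation is that NSD2 may occupy the bodies of transcribed genes, where lysine 36 of histone H3 is methylated; expression in these cells was not analysed here, so it was not tested.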
